A study of Drosophila melanogaster with 3 samples.

How the data were processed

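ChIP-seq against GFP was carried out on 3 biological replicates of whole white prepupae carrying GFP-tagged Hr4, per the labels, with replicate numbers taken from the labels. Chromatin was sheared by sonication to a range of 200 to 800 bp, per the labels. Nothing in the labels splits the replicates into batches, and p-values across peaks, genes or blocks measure no spread between animals.

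The deposited files are narrowPeak lists in builds dm6 and dm3. Per the text files deposited with the samples, a relaxed list of peaks and background was derived from the alignments of each replicate and a control, another from all 3 alignments and a control, and an optimal list by irreproducible discovery rate (IDR) analysis from the 4 relaxed lists. The unit used is the authors' signal value of each peak, as deposited, on the scale of its own list. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here, and read depth is unknown, so no interval that needs depth was computed. Each relaxed list holds 30000 entries, so a replicate's list length says nothing about how many sites it holds. The reproducible lists hold 8693 (dm6) and 8311 (dm3) peaks. All 10 peak lists were read. Builds were never mixed or converted, and dm3 lists were compared only among themselves, with arm ends taken from the highest peak end in the dm3 lists. In dm6, 29 entries share their interval with another entry that has a different summit.

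All positions in dm6 were placed on the Release 6 genome sequence with the Ensembl annotation of that assembly. Each arm's highest peak end lay within the reference length. Promoter classes used the start sites of all annotated transcripts, and distances to a TSS and bound genes those of protein-coding genes. Each summit was assigned to promoter (250 bp to each side of a TSS), 5′ UTR, coding exon, 3′ UTR, exon of a non-coding gene, intron or intergenic sequence, in that order. The class of non-coding exons was added to the 6 planned ones. Analyses of position used the 8687 reproducible peaks on arms 2L, 2R, 3L, 3R, 4 and X. The other 6, on the mitochondrial genome, were left out.

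Overlap counted a peak as found when summits lay within 250 bp, with 95% Wilson intervals for counting error only. Chance was set by 1000 rotations, each moving all summits of an arm by 1 random shift, which keeps their spacing. Rotated and random positions were drawn over whole arms, including long stretches in which no peak was called. How far this shifts the expected shares was not measured. The two-sided p is 2 times the smaller tail, so 0.002 is the smallest it can be. Rank correlations, X against autosomal blocks of 1 Mb and medians of signal used permutation tests with 100000 resamples. Their smallest p is 1e-05 for correlations and medians, and 2e-05 for tests on X, where the smaller tail was doubled. A gene counted as bound when a reproducible summit lay within 1 kb of any of its start sites. The 18 lists were tested by two-sided Fisher's exact test against all other protein-coding genes. 3 of 281 listed symbols did not match a protein-coding gene. Motifs were searched on both strands within 50 bp to either side of the summit and of points 500 bp to its left and right, with the exact McNemar test against the right-hand window. There were 16 motifs. For the direct repeat, Motif 1 and Ohler 6, 1 mismatch was allowed, and all other motifs had to match exactly. Adjustment was by Benjamini-Hochberg within each family, at a threshold of 0.05.

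The text names genes by a fixed rule. It takes the protein-coding gene nearest to each of the 10 strongest peaks and 15 genes of the ecdysone response or of ecdysone synthesis. It adds the 3 genes with the strongest summit in each list that passed, the genes nearest to the 3 peaks whose rank percentile differed most between replicates, and the 5 genes with most summits. This gave 58 genes, of which 1 is not reported here.

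The tests, gene lists, motifs, the rule for named genes and 35 other settings were chosen before the data were examined. Those settings changed the summit distance, promoter and TSS windows, block size, build, motif window, reference for motifs, peak strength, the support asked of replicates and the replicate used, or drew random lists matched on gene length. Another 6 settings were added after the data had been seen: positions, windows and gene lists matched on GC content (200 draws for positions), entries of the pooled list below the reproducible threshold as a set of their own, and the X comparison in each replicate. Leaving out a replicate could be applied to the overlap only, because the reproducible list comes from pooled reads. For gene lists and motifs each replicate's 8693 highest entries were used alone instead.

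The tests of overlap, annotation classes, X against autosomes, gene lists, motifs, rank correlation and signal by class were first tested on simulated data. The tests of the Hr4 region, distance to a TSS, GC content and matched X recovery were not. A simulated overlap of 79.5% was recovered as 79.6%, a promoter share of 40.3% as 40.6%, an X to autosome ratio of 0.6 as 0.6, a planted motif share of 19.2% as 19.2% and a correlation of 0.7 as 0.69. A difference of medians of 0.2 was recovered less closely, as 0.24. Among simulated lists of 30 genes bound at 60% against 25%, 85.5% had an exact p under 0.05 divided by 18, in place of the Benjamini-Hochberg adjustment. Most of the 18 lists held fewer than 30 genes, so this share does not apply to them. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.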

Results

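Binding of Hr4, an orphan nuclear receptor of the ecdysone response, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole white prepupae of Drosophila melanogaster, the stage at which the larva stops moving and the puparium forms. The animals, males and females together, carried Hr4 fused at its C-terminus to green fluorescent protein (GFP), and chromatin was precipitated with an antibody against GFP. The 3 biological replicates formed 1 group, so no conditions were compared. The questions answered are how far the replicates share peaks, where the peaks lie, and near which genes and sequences. Sequencing depth of the replicates is unknown, because the peak lists carry no read counts. No control library was analysed here.

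The reproducible list held 8693 peaks in build dm6, of which 8687 lay on the 6 chromosome arms. Their median width was 424 bp. Each relaxed list, which by design mixes peaks with background, held 30000 entries for each replicate and for the pooled reads. All 8693 reproducible peaks were entries of the pooled relaxed list with the same interval and signal value, and they were exactly its 8693 highest entries. The reproducible list is therefore a rank threshold on pooled reads and not a statement about each peak in each replicate. The signal value is the authors', and it was compared only within 1 list, by rank, value or median. Between replicates, only ranks within each list were compared.

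Most reproducible peaks were found in every replicate. A replicate summit lay within 250 bp of the reproducible summit for 91.7% of peaks in replicate 1 (95% Wilson interval 91.1 to 92.3), 99.1% in replicate 2 (98.9 to 99.3) and 99.5% in replicate 3 (99.3 to 99.6). All 3 replicates held 7863 of 8687 peaks, or 90.5% (89.9 to 91.1), where summits rotated along their arms gave 4.17%. The reproducible peaks were called on the pooled reads of these same replicates, so a share far above the rotated one follows in part from how the list was made. Another 811 peaks were found in exactly 2 replicates, 13 in 1 and 0 in none. Ranks of the 7863 shared peaks were most alike between replicates 2 and 3 (Spearman's rho 0.85, Pearson's r 0.65). Replicate 1 gave rho 0.78 and r 0.52 with replicate 2, and rho 0.80 and r 0.55 with replicate 3. Each of these 3 relations, taken across peaks, which are not independent replicates, had a permutation p of 1e-05 (1e-05 adjusted), the smallest that 100000 resamples can give. The replicate lists were not copies of each other: 1 of 30000 intervals was identical in each pair.

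**Figure D1:**
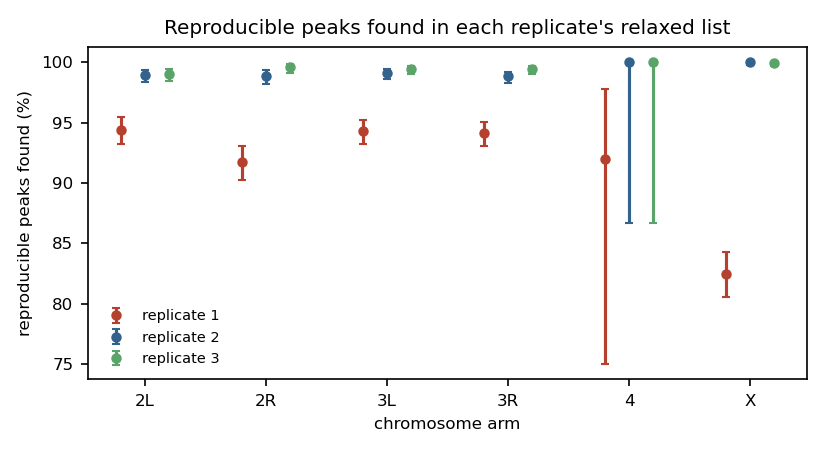
Share of reproducible peaks (vertical axis, percent, starting above 0) with a summit within 250 bp in the relaxed list of each replicate, by chromosome arm; points are single replicates and bars 95% Wilson intervals. Replicate 1 found 82.5% of the X peaks, and replicates 2 and 3 found 100% and 99.9%.

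Replicate 1 stood apart on the X chromosome. It held 1288 of the 1561 reproducible X peaks, 82.5% (95% Wilson interval 80.6 to 84.3), and 93.8% of the peaks of 2L, 2R, 3L and 3R (93.2 to 94.3). Replicates 2 and 3 held 1561 and 1560 of the X peaks. Of the 30000 relaxed entries, 3262 lay on X in replicate 1, 5753 in replicate 2 and 6069 in replicate 3. In 1 Mb blocks the relaxed list of replicate 1 averaged 141.4 entries on X (SD 42.8, 23 blocks) and 243.6 on the autosomal arms (SD 91.4, 108 blocks), a difference of -102.2 (two-sided permutation p = 2e-05, 6e-05 adjusted over the 3 replicates; 2e-05 is the smallest that 100000 resamples can give when the smaller tail is doubled). Replicate 2 averaged 249.4 and 220.2 (permutation p = 0.21, adjusted 0.21), and replicate 3 averaged 263.1 and 216.9 (permutation p = 0.037, adjusted 0.055). The reproducible list averaged 67.8 peaks per Mb on X (SD 27.4) and 65.7 on the autosomal arms (SD 35.2), a difference of 2.10 that did not pass the two-sided permutation test (p = 0.80). Blocks are stretches of genome and not samples. These per-replicate tests were chosen after the data had been seen.

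The Hr4 gene itself carried a series of summits. Hr4 (FBgn0264562) lies on the + strand of X from 1941940 to 2007956 in dm6, and 14 reproducible summits fell within it. With 10 kb to each side, the region held 18 summits, 14 in introns and 4 in promoters of Hr4 or its neighbours, or 0.209 per kb. Rotated summits averaged 0.0658 per kb, and the difference did not pass the two-sided rotation test, a permutation of positions (p = 0.056). Among the stronger 50% of peaks the region held 16 summits, 0.186 per kb against 0.0332 (permutation p = 0.010). The relaxed lists held 19 summits there in replicate 1 and 46 in each of replicates 2 and 3, and none passed (permutation p = 0.38, 0.066 and 0.084). How many copies of this region the transgenic line carries is not given in the sources used here, and reads over it depend on that number. The 2 strongest summits, at 1947764 and 1951911, lay in introns and ranked 155 and 168 of 8693. The promoter summit at 1992400, 100 bp from an annotated start site, ranked 8408. Replicate 1 had no summit within 250 bp of it.

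**Figure D2:**
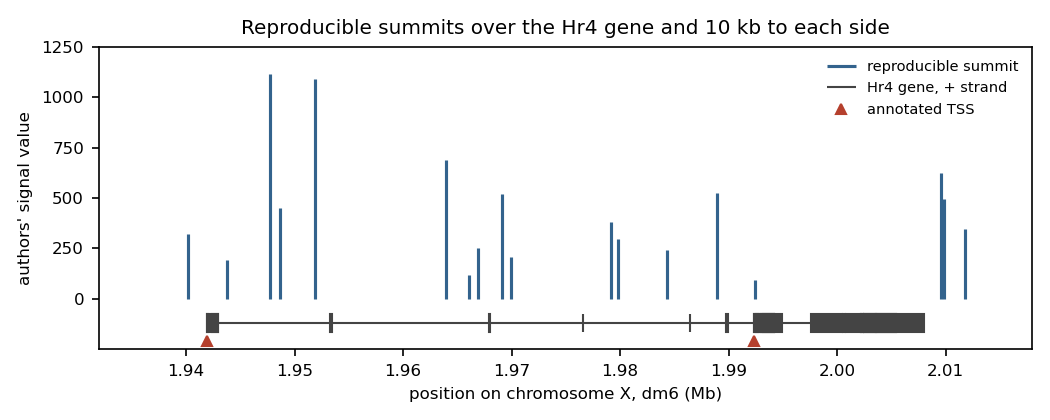
Reproducible summits over Hr4 and 10 kb to each side. The horizontal axis is the position on X (dm6, Mb), blue lines give the authors' signal value of each of the 18 summits, boxes are exons and triangles the annotated start sites at 1941940 and 1992300. The strongest summits, at 1947764 and 1951911, lie in introns.

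Summits favoured promoters and introns and nearly avoided coding sequence. Promoters, defined as 250 bp to each side of a transcription start site (TSS), held 1733 summits, 19.9% (95% Wilson interval 19.1 to 20.8), against 7.49% of rotated summits. Introns held 4724, 54.4% against 41.2%. Intergenic sequence held 1897, 21.8% against 28.6%, and 3′ UTRs held 87, 1.00% against 4.73%. Coding exons held 16 summits, 0.184% (0.113 to 0.299) against 15.5%. These 5 classes each had an adjusted p of 0.0028 by permutation of positions through rotation. 5′ UTRs (1.21% against 1.32%, adjusted permutation p = 0.44) and exons of non-coding genes (1.44% against 1.18%, adjusted permutation p = 0.084) did not pass. Within 1 kb of a protein-coding TSS lay 37.2% of summits (36.2 to 38.2) against 20.2% of rotated ones (permutation p = 0.002). Of those 3231 summits, 2347 (72.6%) lay upstream of the start site. The median position over all 3231 was -148 bp, and the 100 bp bin from -200 to -100 held 688. Promoter summits were also stronger, with a median signal value of 210.1 against 169.9 elsewhere, a difference of 40.1 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Of the 100 strongest peaks, 55 lay in promoters. Peaks are not replicates, and these tests describe 1 pooled list.

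**Figure D3:**
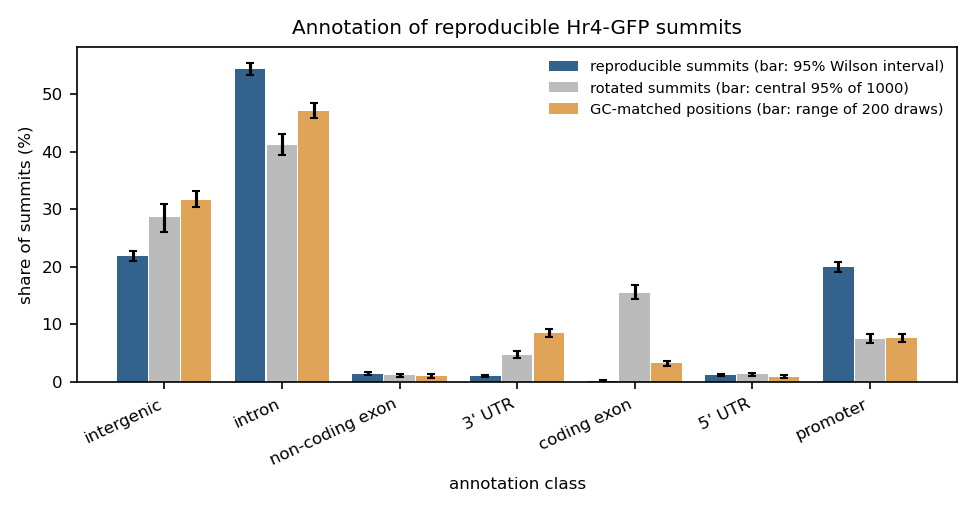
Share of summits (vertical axis, percent) in each of 7 annotation classes. Blue bars are reproducible summits with 95% Wilson intervals, grey bars the mean of 1000 rotations with their central 95%, and orange bars positions matched on GC content with the range of 200 draws. Promoters hold 19.9% of summits against 7.49% of rotated and 7.56% of GC-matched positions, and coding exons hold 0.184% against 15.5% and 3.29%.

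Summits lay in AT-rich sequence. The sequence within 50 bp to either side of a reproducible summit had a mean GC content of 31.7% (SD 7.59 over 8687 summits), against 42.2% for rotated summits (range over 200 rotations 41.8 to 42.6, permutation p = 0.010, the smallest that 200 rotations can give). The flanks were richer in GC, at 44.5% for windows centred 250 bp to the left and 44.8% for those 250 bp to the right. GC content at the summit was also low in each replicate: over the top entries on the arms (8693, 8673 and 8679), its mean was 32.6% in replicate 1, 31.7% in replicate 2 and 32.2% in replicate 3. The 21307 entries of the pooled list below the reproducible threshold, which mix in background, averaged 35.2%. Promoter summits averaged 32.7%, intron summits 31.3% and intergenic summits 31.1%, and the 16 coding exon summits averaged 53.3%. Against positions matched on GC content, promoters (19.9% against 7.56%) and introns (54.4% against 47.2%) were still favoured and coding exons were still avoided (0.184% against 3.29%), each with an adjusted permutation p of 0.012. GC content was examined after the data had been seen.

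**Figure D4:**
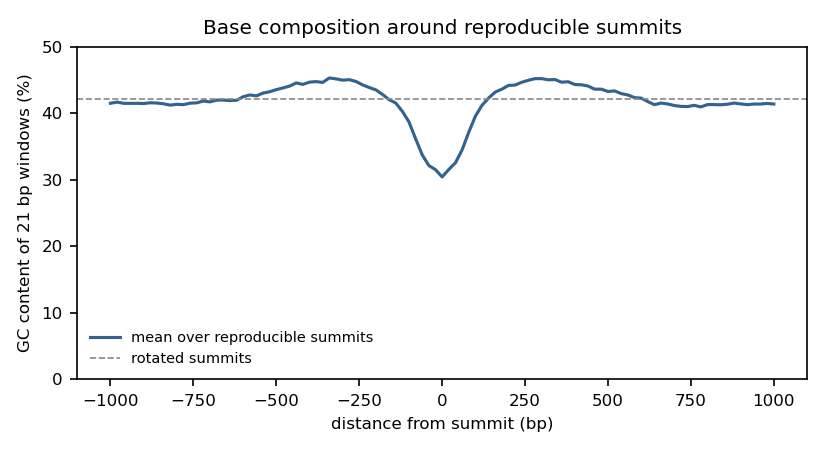
Mean GC content (vertical axis, percent) of 21 bp windows against distance from the summit (horizontal axis, bp), over 8687 reproducible summits; the dashed line is the mean of rotated summits, 42.2%. GC content falls at the summit and rises above the rotated level in both flanks.

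Near which genes summits fell was asked with 18 gene lists. A gene counted as bound when a reproducible summit lay within 1 kb of any of its start sites, as held for 3164 of 13945 protein-coding genes (22.7%). By two-sided Fisher's exact test with adjustment over the lists, 8 lists were bound more often than other genes and 4 less often. Because gene length differs between lists, each was also set against 10000 random lists of the same size. These were matched on 10 classes (deciles) of gene length, so lengths within a class could still differ. By this test 3 lists were above and 1 below. Both tests treat genes as independent. Neighbouring genes of 1 family, such as those of the Enhancer of split complex, need not be. The p-values of lists that hold them may be too small and the Wilson intervals too narrow.

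The lists that stayed above with gene length matched were those of glycolysis, Notch signalling and the ribosome. Glycolysis and lactate genes had 8 of 12 bound (66.7%, 95% Wilson interval 39.1 to 86.2, adjusted exact p = 0.0082), against 26.8% for lists of matched length (adjusted permutation p = 0.039). The strongest were Gapdh2, a glyceraldehyde-3-phosphate dehydrogenase, with signal value 1170, Ldh, lactate dehydrogenase, with 1008, and Eno, enolase, with 949.4. Of Notch signalling and Enhancer of split complex genes 11 of 19 were bound (57.9%, 36.3 to 76.9, adjusted exact p = 0.0082; 23.6% with matched length, adjusted permutation p = 0.0072). E(spl)m3-HLH (603.7) and E(spl)m7-HLH (387.5), transcriptional targets of Notch, and fng (595), a glycosyltransferase that modifies Notch, led that list. Ribosomal protein genes had 34 of 92 bound (37.0%, 27.8 to 47.2, adjusted exact p = 0.0082, against 14.98% with matched length, adjusted permutation p = 0.0018), led by RpS19b (965.3), RpS20 (576.3) and RpL34b (563.4). The summit counted for RpS19b lay 887 bp from its start site, outside that gene and in an intron of another. The ribosomal list did not pass among the stronger 50% of peaks (14.1% bound, adjusted exact p = 1.0) or among peaks found in all 3 replicates (21.7%, adjusted exact p = 0.50), nor did glycolysis within 5 kb of a start site (66.7%, adjusted exact p = 0.20). In replicate 1 alone none of these 3 lists passed, with adjusted exact p of 0.078 for glycolysis, 0.087 for Notch and 0.10 for the ribosome.

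The hormone and metabolic lists were bound more often than other genes but did not pass against genes of their length. Of the ecdysone early and timing genes 14 of 29 were bound (48.3%, adjusted exact p = 0.0082), with an expectation of 32.8% for their length (adjusted permutation p = 0.24). E23, an ecdysone-inducible transporter gene, led with signal value 1024, followed by Ldh, which this list shares with glycolysis, and Eip75B (881.1). Nuclear receptors had 10 of 21 bound (47.6%, adjusted exact p = 0.024, against 35.5% with matched length, adjusted permutation p = 0.43), with Eip75B, Hr96 (691.7) and ERR (543.1), the estrogen-related receptor, the strongest. A summit can count for more than 1 gene: Atg18a, in the autophagy list, had the same value of 543.1. Fat body storage and metabolism genes had 9 of 18 bound (50%, adjusted exact p = 0.020; 29.5% with matched length, adjusted permutation p = 0.24), led by Lpin, a phosphatidate phosphatase, at 1817, Glyp, glycogen phosphorylase, at 883.5, and bmm, a triglyceride lipase, at 642.8. Insulin and growth signalling genes had 12 of 25 bound (48.0%, adjusted exact p = 0.016; 28.0% with matched length, adjusted permutation p = 0.15), among them mTor (412.2) and Pi3K21B (380.0). Circadian clock genes had 7 of 10 bound (70.0%, adjusted exact p = 0.0082; 36.4% with matched length, adjusted permutation p = 0.18), led by the kinase genes sgg (896.5) and dco (270.6) and the photoreceptor gene cry (418.4). Of these 5 lists the ecdysone early and timing genes alone also passed Fisher's exact test at 500 bp, at 5 kb, among the stronger 50% of peaks, among peaks found in all 3 replicates and in each replicate alone. Of the genes named here and for the 3 lists before, the strongest peaks of Gapdh2 and RpS19b had no summit within 250 bp in replicate 1, that of Hr96 none in replicate 2 and that of RpS20 none in replicate 3.

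Odorant, gustatory and ionotropic receptor genes were nearly without summits within 1 kb of a start site. Of 179 such genes, Or88a alone was bound (0.559%, 95% Wilson interval 0.0987 to 3.10, adjusted exact p = 9.67e-18), against 19.0% for lists of matched length (adjusted permutation p = 0.0018). The salivary gland glue and 71E genes had 0 of 22 bound (upper limit of the Wilson interval 14.9%, adjusted exact p = 0.018) and the eggshell genes 0 of 16 (upper limit 19.4%, adjusted exact p = 0.047). Cuticle protein genes had 12 of 97 bound (12.4%, adjusted exact p = 0.024), led by Cpr50Ca (479.7), Cpr66D (274.1) and Cpr49Ah (259.4). By its symbol that list also takes in Cpr, the cytochrome P450 reductase gene. With matched gene length these 3 lists did not pass (10.9%, 13.9% and 15.2% for matched lists, adjusted permutation p = 0.29, 0.29 and 0.56). The remaining lists did not pass Fisher's exact test: ecdysteroid biosynthesis and its regulators (4 of 25 bound, adjusted p = 0.71), programmed cell death (4 of 16, 0.77), autophagy (8 of 22, 0.16), homeotic genes (1 of 8, 0.73), testis-restricted genes (1 of 21, 0.082) and antimicrobial peptides (0 of 14, 0.070).

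**Figure D5:**
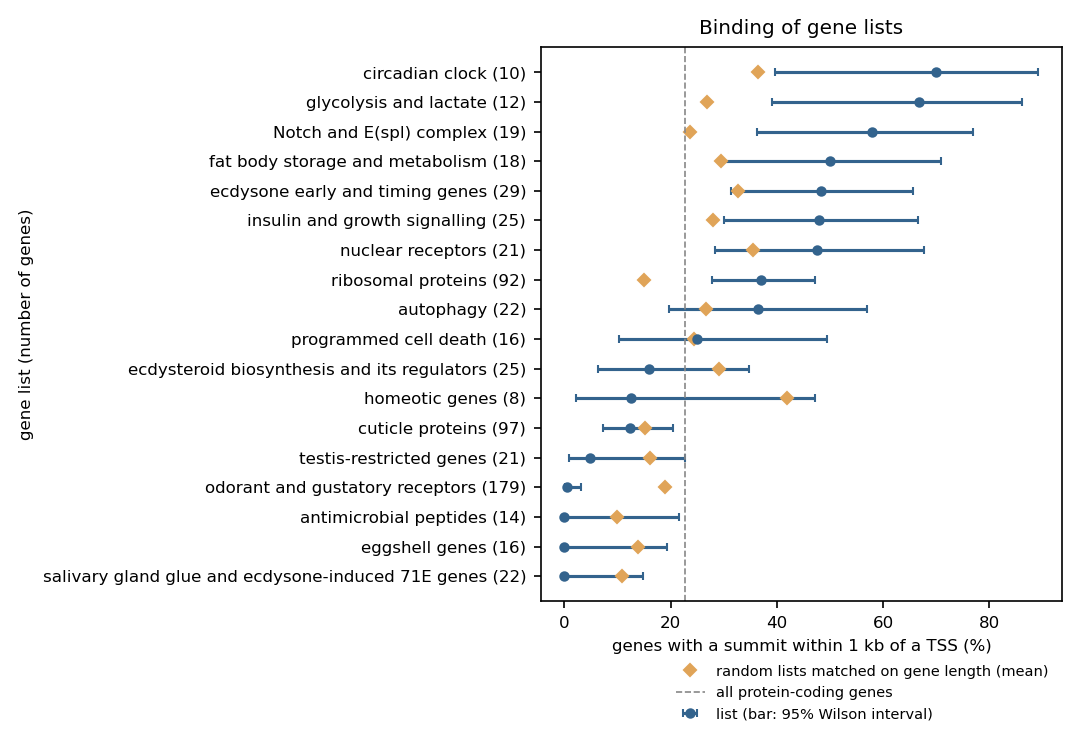
Share of genes with a reproducible summit within 1 kb of a start site (horizontal axis, percent) for 18 lists, with the number of genes in brackets. Blue points carry 95% Wilson intervals, orange diamonds are the mean of random lists matched on gene length, and the dashed line is the share of all protein-coding genes, 22.7%. Ribosomal proteins reach 37.0% against 14.98%, and odorant and gustatory receptors, a list that includes the ionotropic receptors, 0.559% against 19.0%.

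Of 15 genes of the ecdysone response or of ecdysone synthesis fixed in advance, 8 had a summit within 1 kb of a start site. Eip75B (FBgn0000568, 3L 17950953 to 18064696), a nuclear receptor gene induced by ecdysone, carried the strongest, a promoter summit at 17999768 that ranked 297 and stood at the 99.2, 98.9 and 98.8 percentiles of replicates 1, 2 and 3. It held 16 summits between 1 kb upstream and its end. Eip74EF (257, 13 summits in the same span), EcR, the ecdysone receptor (215.2, 11 summits), usp, its partner (229.9, 2 summits), Hr3 (161.8, 10 summits), Blimp-1 (186.9, 3 summits), Eip93F (108.4, 5 summits) and Hr4 (91.17, 14 summits) were also bound. ftz-f1, which encodes a competence factor of the prepupa, had 13 summits in its span, none within 1 kb of a start site (nearest 2917 bp), and br, an early ecdysone gene, had 3 (nearest 3444 bp). The other 5 genes, which encode enzymes of ecdysone synthesis, had no summit in their spans: the nearest lay 2860 bp from a start site of dib, 6727 bp from phm (phtm in the annotation), 12007 bp from Cyp6t3, 213007 bp from nvd and 856637 bp from spok. Around nvd and spok no reproducible summit was called over long stretches, so its absence there is not particular to these genes.

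The 10 strongest peaks had 7 summits in promoters and 3 in introns, and the lowest percentile any of them had in a replicate was 99.95. The strongest lay at 3L 19590402 to 19590858 (signal value 3773), with its summit 88 bp from the start site of CG14100 and the 41 bp around it, on the + strand, reading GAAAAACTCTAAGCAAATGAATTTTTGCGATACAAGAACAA. The next lay at 3R 31404457 to 31404898 (3465), 83 bp from a start site of PNPase, polynucleotide phosphorylase. The third, at 2L 480858 to 481336 (3372), was intronic and 1369 bp from a start site of cbt. The rest were nearest to Ugalt (3363), a UDP-galactose transporter gene, CG11050 (3028), CenG1A (2756), CG18549 (2702), larp (2647), which encodes an RNA-binding protein, Chro (2632), a chromosomal protein of interbands, and CG31145 (2583). The genes with most summits were kirre (32 over 394.1 kb), sbb (30 over 79.1 kb), Snoo (27 over 93.0 kb), CG43658 (26 over 105.0 kb) and mtgo (24 over 118.2 kb). Counted over the gene with 1 kb upstream, that is 0.81 per 10 kb for kirre and 3.74 for sbb, against 0.649 over the arms. The 3 peaks with the widest spread of rank percentiles were nearest to Sox102F (93.4, 89.5 and 0.470 in replicates 1, 2 and 3), Cpr51A (89.95, 60.8 and 1.37) and neb (1.92, 88.3 and 88.9).

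TCAAGGTCA, the extended nuclear receptor motif recognised by GCNF, a vertebrate relative of Hr4, was nearly absent at summits. It occurred within 50 bp to either side of 2 of 8687 summits (0.0230%, 95% Wilson interval 0.00631 to 0.0839) and in 10 right-hand flanks (0.115%), with a mean over both flanks of 0.104% (adjusted exact McNemar p = 0.069 against the right-hand flank). In the top entries of replicate 2 and of replicate 3 and among the stronger 50% of peaks it was less frequent than in the flank (adjusted exact p = 0.021, 0.00087 and 0.035). The core motif AAGGTCA occurred at 0.679% of summits and 0.875% of flanks (adjusted exact p = 0.22). Against windows of the same GC content both motifs turned in direction and neither passed, with TCAAGGTCA in 2 summits and 1 window (adjusted exact p = 1.0) and AAGGTCA in 59 and 54 (adjusted exact p = 0.81). The direct repeat, the Hr3 element, the ecdysone response element, the AP-1 motif and the Zelda motif did not pass either, with adjusted exact p of 0.48, 0.70, 1.0, 0.49 and 0.082. Of the 5 strength classes, the lowest and the middle each held 1 of the 2 summits with TCAAGGTCA, too few to test for a relation with signal.

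Motifs of other DNA-binding proteins and simple repeats differed between summits and flanks. Against the right-hand flank, the DREF motif (0.668% against 0.115%), the BEAF-32 motif (4.32% against 3.04%), Ohler 6 (4.56% against 2.30%) and poly A (5.99% against 4.73%) were more frequent at summits. The GAGA factor motif (0.863% against 2.56%), the longer GA repeat (0.150% against 0.530%), the E-box (0.553% against 1.27%) and the CACA repeat (0.898% against 4.02%) were less frequent. All 8 passed the adjusted exact McNemar test, with p from 1.8e-41 to 0.00048. The DREF motif contains the BEAF-32 motif and the longer GA repeat contains the GAGA factor motif, so these results are not separate. Against copies of the summit sequence with dinucleotides shuffled, GAGA, the GA repeat and CACA were more frequent at summits (adjusted exact p = 2.76e-05, 0.0037 and 0.00013). Against genomic windows matched on GC content none of the 8 passed (adjusted exact p from 0.17 to 1.0). Motif 1, a core promoter element, was then the only one of 16 motifs to differ, at 0.564% of summits against 0.230% (49 against 20 windows, adjusted exact p = 0.010). Promoters held 19.95% of summits but 7.555% of GC-matched positions, and the Motif 1 excess was not separated from this difference in location. Against the flank Motif 1 stood at 0.564% and 0.357% (adjusted exact p = 0.082). The comparison with GC-matched windows was chosen after the data had been seen.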

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

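The reproducible list held 6 peaks on the mitochondrial genome, a sequence that no comparison used. No control samples were analysed here to set that count against. The peaks lay between positions 1575 and 3958, and their ranks ran from 320 to 3361 of 8693. The relaxed lists held 20 mitochondrial entries in replicate 2, 15 in replicate 3 and none in replicate 1. In build dm3 the reproducible list held none. No explanation was tested.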

How the results depend on the processing

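The settings that matched genes, positions or windows on GC content, took the X comparison to each replicate, or used entries below the reproducible threshold were chosen after the data had been seen. Of the results that answer a comparison, 309 values under other settings kept their direction and their side of the threshold, 42 no longer passed, 25 newly passed, 28 turned in direction and 13 counts moved. Of 406 values for single named genes, 370 kept their state, with or without a summit near a start site, and 36 changed it. By number of summits 301 stayed within 1.5 times and 105 moved further. The share of peaks found in every replicate ranged from 90.9% to 98.75% without 1 replicate. The other results could not be recomputed without a replicate, because the reproducible list comes from pooled reads. No paired analysis was possible because the 3 replicates form 1 group. Depth is unknown, so its effect on the number of entries per replicate could not be judged. The causes of the changes that follow were not tested. The p-values of lists are from Fisher's exact test and those of motifs from the exact McNemar test, both adjusted, unless stated.

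With promoters of 1 kb to each side, non-coding exons held 0.437% (adjusted permutation p = 0.77), now below the rotated share, and 5′ UTRs 0.219% (0.0023). Against uniform positions the 1.44% in non-coding exons passed (permutation p = 0.040), as it did against GC-matched positions (0.012), where the 1.21% in 5′ UTRs turned to above the reference (0.020). Among entries below the threshold, intergenic sequence held 28.9% (permutation p = 0.68) and 5′ UTRs 1.51% (0.040), both turned, and non-coding exons 1.59% (0.0028).

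The X minus autosome difference turned to -3.09 in dm3 (permutation p = 0.62) and -102.2 in the relaxed list of replicate 1 (2e-05), and was 46.3 in that of replicate 3 (0.037 before adjustment). The density over the Hr4 region passed with the stronger 50% of peaks, at 0.186 per kb (permutation p = 0.010).

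Within 500 bp of a TSS, nuclear receptors (38.1%, exact p = 0.070), insulin and growth (32%, 0.14) and eggshell genes (0%, 0.076) no longer passed and testis genes did (0%, 0.042). Within 5 kb, 4 lists were above, and nuclear receptors (61.9%, exact p = 0.18), insulin and growth (64%, 0.10), fat body (61.1%, 0.28), glycolysis (66.7%, 0.20) and the clock (80%, 0.083) no longer passed. Autophagy did (72.7%, exact p = 0.025), and cell death (43.75%, 1.0) and homeotic genes (62.5%, 0.51) turned. With the stronger 50% of peaks, 5 lists were above and 2 below. Insulin and growth (32%, exact p = 0.056), glue and 71E (0%, 0.11), fat body (27.8%, 0.24) and eggshell genes (0%, 0.23) were lost, and ribosomal proteins turned (14.1%, 1.0). With peaks found in all 3 replicates, 5 lists were above and 1 below. Nuclear receptors (38.1%, exact p = 0.083), glue and 71E (0%, 0.060), fat body (38.9%, 0.079), ribosomal (21.7%, 0.50), cuticle (12.4%, 0.21) and eggshell genes (0%, 0.0998) were lost.

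In replicate 1 alone, 3 lists were above and 2 below. Insulin and growth (36%, exact p = 0.11), fat body (44.4%, 0.083), glycolysis (50%, 0.078), Notch (42.1%, 0.087), ribosomal (29.3%, 0.10), cuticle (13.4%, 0.098) and eggshell genes (0%, 0.082) were lost. In replicate 2 alone, autophagy (54.5%, exact p = 0.0099), testis genes (0%, 0.0092) and antimicrobial peptides (0%, 0.038) newly passed. In replicate 3 alone, testis genes (0%, exact p = 0.010) and antimicrobial peptides (0%, 0.042) newly passed, fat body was lost (38.9%, 0.19) and homeotic genes turned (25%, 1.0).

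Matched on gene length, 3 lists were above and 1 below. The lists lost, with unchanged shares, were nuclear receptors (47.6%, permutation p = 0.43), ecdysone early and timing genes (48.3%, 0.24), insulin and growth (48%, 0.15), glue and 71E (0%, 0.29), fat body (50%, 0.24), the clock (70%, 0.18), cuticle (12.4%, 0.56) and eggshell genes (0%, 0.29). Matched on GC content, nuclear receptors alone were lost (47.6%, permutation p = 0.081).

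TCAAGGTCA passed as less frequent than in the flank with the stronger 50% of peaks (0%, exact p = 0.035), in replicate 2 (0.0115%, 0.021) and in replicate 3 (0%, 0.00087). AAGGTCA did in replicate 3 (0.691%, exact p = 0.018) and in windows of 100 bp to either side (1.38%, 0.012). In those wider windows AP-1 (1.55%, exact p = 0.011) and Motif 1 (1.52%, 2.46e-05) also passed, as did Motif 1 in replicate 1 (0.667%, 0.016) and Zelda in replicate 2 (0.346%, 0.029). Outside promoters BEAF-32 was lost (3.52%, exact p = 0.21). Changes of direction that did not pass were those of the Hr3 element in replicates 2 (0.288%) and 3 (0.2996%), and the direct repeat against the left-hand flank (0.0461%).

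Against shuffled sequence 8 motifs were above and 1 below. GAGA (0.863%, exact p = 2.76e-05), the GA repeat (0.150%, 0.0037) and CACA (0.898%, 0.00013) turned to above and passed. The direct repeat (0.0461%), the Hr3 element (0.230%) and AP-1 (0.852%) turned without passing. AAGGTCA (0.679%, exact p = 0.012) and Motif 1 (0.564%, 0.0025) newly passed, and the E-box (0.553%, 0.76) was lost. Against GC-matched windows 1 motif was above and 0 below. Motif 1 passed (0.564%, exact p = 0.010). The GA repeat (0.150%, exact p = 1.0), DREF (0.668%, 0.52), BEAF-32 (4.32%, 0.81), the E-box (0.553%, 0.81) and CACA (0.898%, 0.17) were lost. TCAAGGTCA (0.0230%), the direct repeat (0.0461%), AAGGTCA (0.679%), the Hr3 element (0.230%), GAGA (0.863%), Zelda (0.391%), AP-1 (0.852%), Ohler 6 (4.56%) and poly A (5.99%) turned without passing.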

Other observations

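Gene families defined only by the letters that open their symbols were scanned after the data had been seen, over 30 families of at least 20 genes. Among families of ribosomal genes, those of the small subunit of the mitochondrial ribosome, mRpS, alone passed Fisher's exact test. Summits lay within 1 kb of a start site for 13 of 26 mRpS genes (50%, adjusted Fisher's exact p = 0.014), against 13.4% for lists of matched gene length (adjusted permutation p = 0.0015). For mRpL genes the count was 17 of 47 (36.2%, adjusted exact p = 0.12; 12.2% with matched length, adjusted permutation p = 0.0015). The cytosolic RpL genes had 18 of 50 (36%, adjusted exact p = 0.12; 15.4% with matched length, adjusted permutation p = 0.0040) and RpS genes 14 of 38 (36.8%, adjusted exact p = 0.12; 15.2%, adjusted permutation p = 0.0087). At the other end, ppk ion channel genes had 0 of 28 (adjusted exact p = 0.0066), 2 histone genes were bound (1.74%, adjusted exact p = 4.17e-09) and Cyp genes, the cytochromes P450, had 9 of 85 (10.6%, adjusted exact p = 0.023). Histone genes are near-identical repeated copies that can share reads, so their count is uncertain. Genes of 1 family can also be neighbours, and these tests treat them as independent. In all, 1 family was above and 7 below other genes, and with matched length 4 were above and 7 below.

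Of the tests of explanations that follow, those of general weakness in replicate 1, those on the share of all X peaks found and both of those on AT-rich summits were chosen after the result had been seen. Each pattern was found and tested on the same data.

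Replicate 1 found fewer X peaks than the other replicates. A generally weaker precipitation would lower autosomal peaks of the same strength alike, but the X share was -11.24 percentage points from that of autosomal peaks of the same pooled signal (82.5% against 93.75%, permutation p = 2e-05, the smallest that 100000 resamples can give when the smaller tail is doubled), close to the gap without matching. Loss of a few regions is argued against too: among peaks found in all 3 replicates, 91.7% of the 24 blocks of 1 Mb had lower ranks in replicate 1 than the autosomal median, and over all 1561 X peaks 22 blocks had a lower share found than the autosomes. Less X-chromosome DNA in the animals of replicate 1, as a higher share of males would give, may account for it: in each strength class, from weakest to strongest, X differed from the autosomes in rank percentile by -4.48, -3.10 and -0.99 among peaks that all 3 replicates held, and in the share found by -14.8, -9.13 and -9.91 percentage points over all peaks. Weaker binding along the whole X in that replicate would look the same, and the sex ratio of the replicates is not given in the sources used here.

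Summits lay in AT-rich sequence and almost never in coding exons. Calling of AT-rich sequence whatever gene it lies near is argued against, as the whole cause, by odorant, gustatory and ionotropic receptor genes. Genes were matched on the lowest GC content of any short stretch within 1 kb of their start sites, not on the start sites themselves. The bound share of receptor genes was -19.07 percentage points from that of matched genes (19.6%, permutation p = 0.0002, the smallest that 10000 lists can give, and 0.0036 adjusted over all 18 lists, since this list was picked for its low share). Avoidance of coding exons is not enough either, since summits had a GC content -8.95 percentage points from that of positions in the same annotation classes (31.7% against 40.6%). A base composition bias of the libraries that acts within open chromatin remains open, because control reads were not analysed here, and no biological explanation was tested.

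Summits showed no excess of the core motif AAGGTCA. Low GC content at summits could hide one. The motif was less frequent there than in copies of the same windows with dinucleotides shuffled. It was found only in the summit for 57 windows and only in the copy for 91, a ratio of 0.626 (exact 95% limits 0.442 to 0.882, exact McNemar p = 0.0065). The shuffled copies held the motif in 93 windows, more than both the summits (59) and genomic windows of the same GC content (54). The deficit against shuffled copies is therefore not particular to summits. It cannot decide whether low GC content hid an excess. Against genomic windows of the same GC content the ratio of all windows with the motif, 59 to 54, was 1.09. Its limits were 0.743 to 1.61, so an excess of up to 1.61 times is not excluded there. For TCAAGGTCA the counts, 2 and 1, are too few to decide. Whether Hr4 reaches these sites through other proteins, or the peaks reflect open chromatin, was not tested, and the design, with its single group, gave no biological explanation to test.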
